A study of Mus musculus with 6 samples.

How the data were processed

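RNA from sorted leukaemia initiating cells (LICs) of mice was sequenced in 6 libraries, 3 labelled adult and 3 labelled neonatal. Per the labels' protocols, Trizol RNA was polyA-selected, made into libraries with a kit that does not mark strand, and read single-end on an Illumina HiSeq instrument. The deposited values were raw read counts per gene, made per the file headers with featureCounts v1.5.1 counting primary alignments by gene identifier, without a strand option, on a UCSC gene annotation of mouse build mm10. The submitters' processing notes also name Trimmomatic, Bowtie, TopHat and DESeq2, without versions. No DESeq2 values were in the file used here. The 13 mitochondrially encoded genes were absent from the file. Gene coordinates are those of the file, with a gene's lowest start and highest end.

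The file held 23337 genes. Library totals were 60113466, 65183188 and 62308393 counts for adult replicates 1, 2 and 4, and 3932833, 64712241 and 66132051 counts for neonatal replicates 4, 7 and 8. CPM values used effective library sizes after TMM scaling. A count of 0 was given a floor of 3 counts (95% confidence). On library totals without TMM scaling this is 0.763 CPM in neonatal replicate 4 and 0.0454 to 0.0499 CPM in the others. For a gene with 0 counts in a group the fold is stated as at least the value at 3 counts over the group, with TMM scaling. These floors and the ratio intervals cover counting error only.

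Neonatal LICs were compared with adult LICs, neonatal minus adult, with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM, a robust quasi-likelihood fit and its F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 13272 genes, and the common biological coefficient of variation was 0.531. Log2 fold changes used edgeR's fitted values, and log2 CPM for correlations and principal components used a prior count of 2. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. It is therefore an approximate value derived from the test and not a standard error fitted by the model. Group values are means of CPM with SD over 3 libraries.

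Gene lists, 33 in number with 787 genes of which 768 were in the file, were fixed before the data were examined, and 10 older gene symbols were matched through synonyms. Of these lists 31 had at least 3 tested members. They were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. Adjustment over the list alone took the edgeR p-values of a list's members by themselves.

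The rule for named genes was fixed at the same time. Its parts were, per direction, up to 12 genes with the largest log2 fold change among those past the threshold, without overlap between the groups and with a mean of at least 2 CPM in the higher group, predicted genes and pseudogenes passed over; up to 4 members of each called list with the smallest adjusted p in the list's direction; up to 2 called members of every other list; and 17 genes in every case. Of the 17, 1 is not reported here, and the others were Lin28b, Igf2bp3, Hmga2, Hoxa9, Meis1, Ebf1, Csf1r, Mpo, Kit, Cd34, Ccl5 and, as checks of the labels, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Members of called lists that this rule picked but that are not described below were Ctnnal1, Csf3r, Cd63, Gfi1, Mpeg1, H2-DMb1, H2-T23, Psmb10 and Nr4a2. Also not described were Jund, Jun, Ppan, Polr1b, Rcl1, Aldoa and Pfkm. None of these passed over all genes on 6 libraries, and Jun, Polr1b, Rcl1 and Pfkm overlapped between the groups. Genes of the fit without neonatal replicate 4 and those said to be chosen after their values were seen fall outside this rule.

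Alternatives planned with the design were DESeq2 1.42.0, limma voom, edgeR's likelihood ratio test, a fit that was not robust, 4 other scalings, 3 other filters, chromosomes X and Y left out, and each library left out in turn. Added after the low depth of neonatal replicate 4 was seen were limma voom with library quality weights, all libraries thinned to that depth, DESeq2 or an estimated correlation without that replicate, and offsets that remove each library's trend on exon length and GC content. GC content came from GENCODE transcripts of the same mouse assembly and was found for 98.6% of the genes kept.

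The fits were tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 50 genes at each of 4 fold sizes. For neonatal minus adult with 6 libraries and 13084 genes, edgeR called 1, 16, 40 and 49 of 50 genes at absolute log2 fold changes of 1, 2, 3 and 5, and 11 of 12884 unchanged genes. With neonatal replicate 4 left out (13549 genes) it called 7, 32, 47 and 45 of 50, and 14 of 13349 unchanged genes. A shift of -2 given to the maturing neutrophil list in simulated counts of 13272 genes was called by camera with a median of -2.01, with 0 other lists called. Genes were drawn independently of each other, so this test does not show how often camera calls lists whose members vary together.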

Results

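The data were gene-level read counts from polyA-selected RNA-seq of sorted leukaemia initiating cells (LICs), the leukaemia cells able to start the disease anew, from mouse leukaemias of adult or neonatal origin. The labels give haematopoietic stem and progenitor cells as the source material. There were 3 adult libraries (replicates 1, 2 and 4) and 3 neonatal libraries (replicates 4, 7 and 8). The adult libraries held 60113466, 65183188 and 62308393 counts, and neonatal replicates 7 and 8 held 64712241 and 66132051. Neonatal replicate 4 held 3932833 counts, and the other 5 held 16.2 times as many on average. A gene with no count in a library was therefore given a floor of 3 counts, which covers counting error only. Without TMM scaling this was 0.763 CPM (counts scaled to library size) in neonatal replicate 4 and at most 0.0499 CPM in the others. The labels name neither the driver of the leukaemia nor the sex of the mice. They also do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

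Adult and neonatal replicates formed separate groups except for neonatal replicate 4. Pearson correlations of log2 CPM across the 13272 genes kept, which are not independent replicates, were 0.926 to 0.946 within the adult group and 0.954 between neonatal replicates 7 and 8. Neonatal replicate 4 had a correlation of 0.880 with neonatal replicate 7 and 0.865 with neonatal replicate 8, and of 0.857 to 0.875 with the adult libraries. Rn45s, the 45S ribosomal precursor gene whose RNA polyA selection largely removes, stood at 1463, 1219 and 1164 CPM in adult replicates 1, 2 and 4, at 1870 CPM in neonatal replicate 4, and at 3549 and 3536 CPM in neonatal replicates 7 and 8.

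**Figure D1:**
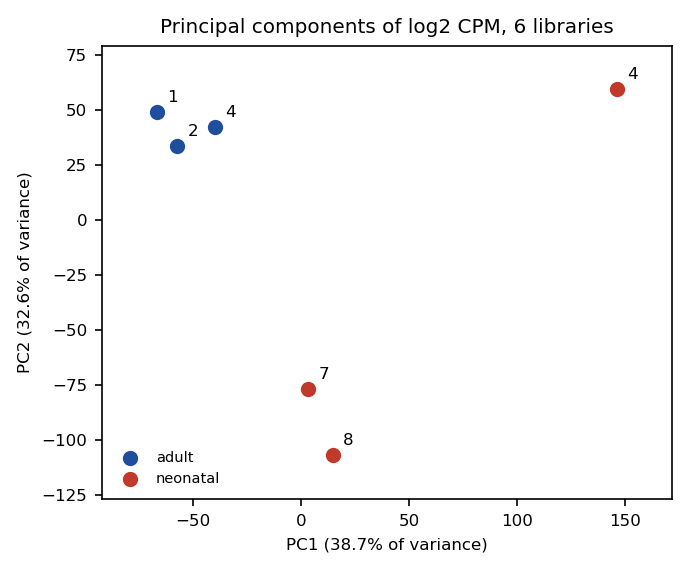
First 2 principal components of log2 CPM over 13272 genes, with the score on each component on the axes, 1 point per library, blue for adult and red for neonatal, and replicate numbers beside the points. PC1 (38.7% of the variance) sets neonatal replicate 4 apart at 146. PC2 (32.6%) places neonatal replicates 7 and 8 at -76.9 and -107 and the adult libraries between 33.5 and 48.8. On PC2 neonatal replicate 4 lies on the adult side, at 59.3.

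The comparison asked how LICs of neonatal leukaemia differ from those of adult leukaemia. As lists, stem and early progenitor, lymphoid-primed progenitor, antigen presentation and glycolysis genes were higher in neonatal LICs, and genes that are switched on as granulocytes mature were higher in adult LICs, by camera with its preset correlation. Of 31 lists tested, 10 passed in this way, 0 passed with an estimated correlation and 1 (MHC class I) passed fry. Gene by gene, 7 of 13272 genes passed edgeR's quasi-likelihood test on all 6 libraries, 5 of them on the sex chromosomes. With neonatal replicate 4 left out, 828 of 13856 genes passed.

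The 7 genes were Xist and Pi15, higher in neonatal LICs, and Eif2s3y, Kdm5d, Ddx3y, Uty and Cftr, higher in adult LICs. Xist (chromosome X, 103460373 to 103483233, mm10), the RNA that silences an X chromosome in female cells, was at 185.9, 51.7 and 58.0 CPM in neonatal replicates 4, 7 and 8 and at 0.610 to 0.919 CPM in the adult libraries (log2 fold change 7.02 ± 0.68, SE, edgeR adjusted p = 0.0236). This call was lost without adult replicate 1, 2 or 4 (adjusted p from edgeR, limma or DESeq2 over 21 alternatives 1.19e-90 to 0.280). Xist overlaps its antisense partner Tsix, and the library kit does not mark strand. The 4 Y-linked genes were expressed in all 3 adult libraries, with Ddx3y at 98.7 to 154 CPM and Eif2s3y at 125 to 154 CPM. In the neonatal libraries together, Eif2s3y and Kdm5d had 0 counts, Ddx3y had 1 and Uty had 3. Every adult library thus carried Y-linked RNA and every neonatal library carried Xist RNA, so the sex of the cells and the age group went together in all 6 libraries.

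Cftr and Pi15 were the called genes outside chromosomes X and Y. Cftr (chromosome 6, 18170687 to 18322769), the chloride channel gene mutated in cystic fibrosis, stood at 145, 39.0 and 62.8 CPM in adult replicates 1, 2 and 4 and had 0 counts in the 3 neonatal libraries, at least 3774-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0486). Pi15 (chromosome 1, 17601901 to 17630939), which encodes a peptidase inhibitor, averaged 12.3 ± 5.56 CPM (SD, n = 3) in neonatal and 0.337 ± 0.0615 CPM (SD, n = 3) in adult LICs, a log2 fold change of 5.16 ± 0.60 (SE, edgeR adjusted p = 0.0486). Both calls were lost when any library other than neonatal replicate 4 was left out. Neither gene passed with chromosomes X and Y left out before the fit, because the sex-linked genes had ranked ahead of both. Over 22 alternatives the adjusted p from edgeR, limma or DESeq2 ran from 1.57e-21 to 0.308 for Pi15 and from 2.63e-28 to 0.143 for Cftr.

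Genes of stem cells, early progenitors and lymphoid-primed progenitors were higher as lists in neonatal LICs. Of 14 tested stem and early progenitor genes, 11 had a positive log2 fold change (median 0.67, camera adjusted p = 0.0163, adjusted p = 0.559 with an estimated correlation), and none passed the test over all genes or adjusted over the list alone. The list was not called without adult replicate 4 (camera and fry adjusted p over 16 alternatives 7.83e-05 to 0.559). The other 11 of the 25 listed genes, Procr, Slamf1 and Fgd5 among them, were too low to be tested. Hlf and Ly6a, stem cell genes chosen after their values were seen, went the other way, at 1.55 ± 0.997 and 4.39 ± 3.92 CPM in adult and 0.109 ± 0.188 and 1.63 ± 1.44 CPM in neonatal LICs (SD, n = 3 each). Cd34, a surface marker of progenitors, averaged 567 ± 148 CPM (SD, n = 3) in neonatal and 42.0 ± 54.9 CPM (SD, n = 3) in adult LICs. Gata2, a transcription factor of stem cells, was at 11.95, 123.6 and 483.5 CPM in neonatal replicates 4, 7 and 8 and at 1.012 to 16.47 CPM in the adult libraries. Prdm16, which supports stem cell maintenance, averaged 16.3 ± 2.51 CPM against 1.21 ± 1.97 CPM (SD, n = 3 each). Kit, the stem cell factor receptor gene, was at 264 and 186 CPM in neonatal replicates 7 and 8, at 50.03 to 85.79 CPM in adult LICs and at 23.6 CPM in neonatal replicate 4. Without that replicate its log2 fold change was 1.75 (edgeR adjusted p = 0.0361, range over 22 alternatives 2.41e-06 to 0.876).

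Of 15 lymphoid-primed progenitor genes, 11 had a positive log2 fold change (median 0.96, camera adjusted p = 0.00395, adjusted p = 0.559 with an estimated correlation). Of the 19 listed genes, Rag1, Dntt, Ikzf3 and Ccr9 were too low in most libraries to be tested, Rag1 with 0 counts in every library. Ly6d averaged only 0.464 CPM in neonatal and 0.0167 CPM in adult LICs. Il7r overlapped between the groups, at 1.544 to 13.39 CPM in neonatal and 0.6853 to 2.144 CPM in adult LICs. Adjusted over the list alone, Flt3 and Satb1 were higher and Bcl11a lower, while none passed over all genes. Flt3 is also a member of the dendritic cell list. Flt3 (chromosome 5, 147330742 to 147400489), the receptor tyrosine kinase gene of early and lymphoid-primed progenitors, was at 256, 568 and 1230 CPM in neonatal replicates 4, 7 and 8 and at 4.579 to 19.35 CPM in adult LICs (log2 fold change 6.07 ± 0.87, SE, edgeR adjusted p = 0.133). Satb1, a chromatin organiser that promotes lymphoid fate, was at 35.57, 46.17 and 212.5 CPM against 1.41 to 1.76 CPM (log2 fold change 5.91 ± 0.81, SE, edgeR adjusted p = 0.119). Both passed without neonatal replicate 4, at edgeR adjusted p-values of 0.0348 and 0.0320, and both also passed with it once each library's trend on gene length and GC content was removed (0.0265 for each). Over 22 alternatives their edgeR, limma or DESeq2 adjusted p ran from 1.57e-21 to 0.390 for Flt3 and from 7.21e-23 to 0.390 for Satb1. Bcl11a, chosen after its values were seen and a transcription factor of lymphoid progenitors, moved the other way, with 0.530 to 2.89 CPM in adult LICs and 0 counts in the neonatal libraries. B lymphoid markers showed no shift as a list (12 tested, median 0.01, camera adjusted p = 0.743), and adjusted over the list alone 2 members were lower in neonatal LICs. Ebf1, a regulator of B cell commitment, had 6 counts, all in neonatal replicate 7.

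**Figure D2:**
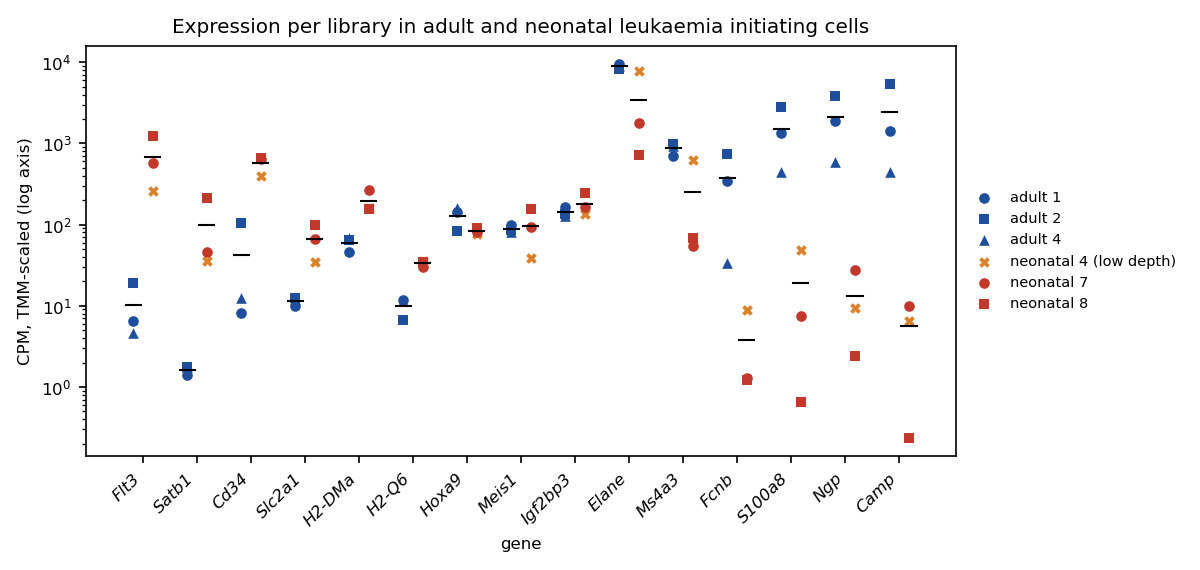
CPM per library on a log axis for 15 genes, blue for adult and red or orange for neonatal libraries, with a marker shape per replicate and black bars at the group means (n = 3). Flt3, Satb1, Cd34 and Slc2a1 lay higher in each neonatal library than in each adult library, Ngp, Camp, S100a8 and Fcnb lay lower, and Elane and Ms4a3 in neonatal replicate 4 (orange crosses, 7805 and 625 CPM) lay near the adult values.

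Maturing neutrophil genes were lower in neonatal LICs, and all 19 tested members had a negative log2 fold change (median -1.95, camera adjusted p = 2.66e-07, adjusted p = 0.559 with an estimated correlation). None passed over all genes, and 5 passed adjusted over the list alone: Ngp, Camp, Ltf, S100a8 and S100a9. The secondary granule genes Ngp and Camp averaged 2125.5 ± 1665 and 2414 ± 2619 CPM in adult LICs and 13.10 ± 13.05 and 5.62 ± 4.98 CPM in neonatal LICs (SD, n = 3 each, edgeR adjusted p = 0.1404 for each). S100a8 and S100a9, whose proteins form calprotectin, averaged 1525 ± 1176 and 1096 ± 980 CPM in adult and 19.2 ± 26.3 and 11.9 ± 13.4 CPM in neonatal LICs (SD, n = 3 each). The adult libraries differed widely among themselves, with Camp at 1413, 5386 and 444 CPM in replicates 1, 2 and 4. Over 16 alternatives the list's adjusted p in camera or fry ran from 7.79e-14 to 0.958. The falls were uneven among members. Cxcr2, Mmp8, Mmp9 and Padi4, chosen after their values were seen, had log2 fold changes of only -0.09, -0.31, -0.38 and -0.15, against -8.77 for Camp. Genes of this list also mark mature neutrophils, a cell type that sorting can carry along.

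Of 20 granulocyte-monocyte progenitor genes, 12 had a negative log2 fold change (median -0.19, camera adjusted p = 0.0400, adjusted p = 0.686 with an estimated correlation), and Fcnb alone passed adjusted over the list alone. The list was not called without adult replicate 1 or 2 or without neonatal replicate 7 or 8 (camera and fry adjusted p over 16 alternatives 0.00062 to 0.686). Without neonatal replicate 4 its median was -0.81, with 5 members lower by edgeR over all genes, and 9 lower and 2 higher adjusted over the list alone. Fcnb, which encodes a ficolin of immature granulocytes, averaged 374 ± 358 CPM in adult and 3.82 ± 4.46 CPM in neonatal LICs (SD, n = 3 each, log2 fold change -6.92 ± 1.41, SE, edgeR adjusted p = 0.1404). Without neonatal replicate 4 its log2 fold change was -8.22 (edgeR adjusted p = 0.0446, range over 22 alternatives 2.44e-08 to 0.412). Elane, the neutrophil elastase gene, and Ms4a3, a granulocyte-monocyte progenitor marker, were both chosen after their values were seen. Elane was at 8255 to 9474 CPM in adult LICs, at 1785 and 726 CPM in neonatal replicates 7 and 8, and at 7805 CPM in neonatal replicate 4. Ms4a3 followed the same pattern, with 693 to 996 CPM in adult LICs, 53.88 and 69.05 CPM in neonatal replicates 7 and 8, and 625 CPM in neonatal replicate 4. Without replicate 4 both fell in neonatal LICs (log2 fold changes -2.82 and -3.82, edgeR adjusted p = 0.0360 and 0.00745, ranges over 22 alternatives 2.77e-10 to 0.839 and 3.848e-45 to 0.7885). Mpo, the myeloperoxidase gene, varied from 60.95 to 1980 CPM among neonatal and from 1097 to 10360 CPM among adult libraries (edgeR adjusted p = 0.528).

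Monocyte and macrophage genes were lower as a list in neonatal LICs, with 18 of 26 negative (median -1.13, camera adjusted p = 0.0209, adjusted p = 0.743 with an estimated correlation), but its members went both ways. Adjusted over the list alone, Emr4, Fcgr1 and Cd300lf were lower, and Cd68 and Irf8, both chosen after their values were seen, were higher. Cd300lf, an inhibitory receptor gene of myeloid cells, averaged 44.9 ± 28.1 CPM in adult and 5.26 ± 3.66 CPM in neonatal LICs (SD, n = 3 each). Irf8, a transcription factor of monocyte and dendritic cell fate, averaged 75.4 ± 49.3 CPM in adult and 336 ± 46.6 CPM in neonatal LICs (SD, n = 3 each, log2 fold change 2.15, edgeR adjusted p = 0.165). Csf1r, the macrophage growth factor receptor gene, averaged 40.3 ± 17.2 and 46.1 ± 31.3 CPM (SD, n = 3 each, log2 fold change 0.20, edgeR adjusted p = 0.936). The list was not called without neonatal replicate 4 (camera adjusted p = 0.0801, range over 16 alternatives 0.00022 to 0.958). It was also lost without adult replicate 1 or 2, without neonatal replicate 8, with a stricter filter and with all libraries thinned.

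Antigen presentation genes were higher as lists in neonatal LICs. All 9 tested MHC class II genes (median 1.60, camera adjusted p = 5.27e-05, adjusted p = 0.559 with an estimated correlation) and all 14 MHC class I genes (median 0.93, camera adjusted p = 2.13e-05, adjusted p = 0.211 with an estimated correlation) had a positive log2 fold change. None passed over all genes, and 3 class II and 2 class I members passed adjusted over the list alone. H2-DMa, which helps load peptides onto class II molecules, averaged 193 ± 60.5 CPM in neonatal and 59.5 ± 12.1 CPM in adult LICs (SD, n = 3 each, log2 fold change 1.70 ± 0.34, SE, edgeR adjusted p = 0.1404). H2-Oa, which tunes that loading, averaged 11.4 ± 6.74 and 1.79 ± 0.213 CPM (SD, n = 3 each). H2-Ab1, a class II chain gene, averaged 45.1 ± 5.16 and 21.7 ± 3.86 CPM (SD, n = 3 each). H2-Aa, H2-Eb1 and Cd74, chosen after their values were seen, were low in most libraries. H2-Aa averaged 2.19 CPM in neonatal and 0.719 CPM in adult LICs, and H2-Eb1 1.03 and 0.423 CPM. Cd74 was at 0, 15.6 and 0.874 CPM in neonatal replicates 4, 7 and 8 and at 0.125 to 1.37 CPM in adult LICs. Ciita and H2-Eb2 were too low to be tested in 6 libraries. Psmb8, a subunit of the immunoproteasome, averaged 682 ± 158 and 274 ± 43.5 CPM (SD, n = 3 each, log2 fold change 1.31 ± 0.31, SE, edgeR adjusted p = 0.164). H2-Q6 averaged 33.4 ± 2.81 and 9.92 ± 2.84 CPM (SD, n = 3 each), and its reads are hard to tell from those of its near-identical neighbours. Tap1, Tap2 and Tapbp, the peptide transporter genes and the gene of their partner tapasin, were chosen after their values were seen. B2m, the light chain gene of class I molecules and also chosen after its values were seen, was at 3005, 1069 and 704 CPM in neonatal replicates 4, 7 and 8 and at 877 to 1189 CPM in adult LICs, and its log2 fold change of 0.65 turned to -0.18 without neonatal replicate 4. Tap2 was at 659 and 584 CPM in neonatal replicates 7 and 8, at 114.6 to 168.7 CPM in adult LICs and at 40.95 CPM in neonatal replicate 4. Without replicate 4 all 3 rose in neonatal LICs (log2 fold changes 1.76, 2.15 and 1.66, edgeR adjusted p = 0.0360, 0.0273 and 0.0320, range over 22 alternatives 5.32e-16 to 0.8255 for Tap2). MHC class I was the 1 list that fry called (adjusted p = 0.00758). Over 16 alternatives its adjusted p in camera or fry ran from 7.34e-07 to 0.441.

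Glycolysis genes were higher as a list in neonatal LICs, with 18 of 21 positive (median 0.57, camera adjusted p = 7.58e-05, adjusted p = 0.559 with an estimated correlation) and Slc2a1 and Aldoc past the threshold adjusted over the list alone. Slc2a1, the main glucose transporter gene, averaged 66.3 ± 32.2 CPM in neonatal and 11.5 ± 1.36 CPM in adult LICs (SD, n = 3 each, log2 fold change 2.53 ± 0.44, SE, edgeR adjusted p = 0.1404). Aldoc, an aldolase gene, averaged 19.1 ± 14.6 and 1.76 ± 0.292 CPM (SD, n = 3 each, log2 fold change 3.45 ± 0.66, SE). Both rose in the fit without neonatal replicate 4 (edgeR adjusted p = 0.0206 and 0.0320, ranges over 22 alternatives 5.23e-20 to 0.390 and 6.46e-14 to 0.390). MYC and ribosome biogenesis genes had 22 of 25 positive (median 0.52, camera adjusted p = 0.00864, adjusted p = 0.814 with an estimated correlation), and none passed adjusted over the list alone. This list was not called without adult replicate 2 (camera and fry adjusted p over 16 alternatives 0.000103 to 0.958). Myc itself averaged 391 ± 92.6 CPM in neonatal and 176 ± 100 CPM in adult LICs (SD, n = 3 each, edgeR adjusted p = 0.424). Immediate early genes, which also respond to cell handling, had 11 of 18 positive (median 0.40, camera adjusted p = 0.0286, adjusted p = 0.825 with an estimated correlation), and Dusp2, a phosphatase that shuts off MAP kinases, passed adjusted over the list alone at 83.6 ± 46.9 against 21.8 ± 1.47 CPM (SD, n = 3 each). The immediate early list was not called without neonatal replicate 4 (camera adjusted p = 0.133) or with length and GC trends removed (0.512), within a range over 16 alternatives of 0.00858 to 0.958. It was also lost without adult replicate 4 and with quality weights.

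The fetal and neonatal program was not called as a list (9 of 24 genes tested, median -0.38, camera adjusted p = 0.296), and no member passed adjusted over the list alone. Igf2bp3, an RNA-binding protein gene of fetal blood cells, averaged 181 ± 56.0 CPM in neonatal and 143 ± 21.0 CPM in adult LICs (SD, n = 3 each, log2 fold change 0.34 ± 0.32, SE, edgeR adjusted p = 0.747). Hmga2, a chromatin protein gene of fetal stem cells, averaged 10.2 ± 8.02 and 7.12 ± 1.67 CPM (SD, n = 3 each), and its sign turned to -0.31 without neonatal replicate 4. Lin28b, which promotes the fetal state of blood stem cells, had 25 counts over the adult libraries and 0 over the neonatal ones and was too low to be tested. Nearly all of these counts were in adult replicate 1 (0.385 CPM, against 0.0149 and 0.0156 CPM in adult replicates 2 and 4). The HOXA and MEIS1 leukaemia program was likewise not called (22 tested, median -0.13, camera adjusted p = 0.841). Hoxa9 averaged 83.1 ± 7.84 CPM in neonatal and 128 ± 39.2 CPM in adult LICs (SD, n = 3 each, log2 fold change -0.63 ± 0.32, SE, edgeR adjusted p = 0.508). Meis1, whose protein binds DNA together with HOXA9, averaged 96.7 ± 59.2 and 87.8 ± 8.85 CPM (SD, n = 3 each, edgeR adjusted p = 0.943).

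Markers of other cell types that a sort could hold were not called as lists: T cell (median 0.08), dendritic cell (0.04), erythroid (-0.54), megakaryocyte and platelet (0.17), mast cell, basophil and eosinophil (-0.67), and stroma and endothelium (-0.23), at camera adjusted p-values of 0.718, 0.134, 0.636, 0.646, 0.636 and 0.718. The camera direction was upward for stroma and endothelium against a negative median, and upward for T cell markers against a mean of -0.78. No member of these lists passed over all genes with all 6 libraries. Adjusted over the list alone, Cd200r3 (mast cell, basophil and eosinophil), Pdgfrb (stroma) and Flt3 (dendritic cell) were higher in neonatal LICs, and Tcf7 (T cell), Ccr3 and Mitf (both mast cell, basophil and eosinophil) were lower. All but Flt3 were named after their values were seen. Without neonatal replicate 4, Flt3 and Pdgfrb passed over all genes as higher and Tcf7 as lower in neonatal LICs (edgeR adjusted p = 0.0348, 0.0375 and 0.0420). Pdgfrb, a growth factor receptor gene of stromal cells, averaged 60.03 ± 48.15 CPM in neonatal and 7.65 ± 4.90 CPM in adult LICs (SD, n = 3 each, edgeR adjusted p = 0.195). Cd200r3 averaged 2.42 ± 1.88 CPM (SD, n = 3) in neonatal LICs with 0 counts in adult LICs, and Tcf7, a transcription factor of T cells and progenitors, had 0.774 to 1.51 CPM in adult LICs and 0 counts in neonatal LICs. The proliferation lists were not called either: DNA replication (median 0.15, camera adjusted p = 0.853), mitosis (0.07, 0.837) and cell cycle inhibition (-0.13, 0.853). Mki67, a marker of dividing cells chosen after its values were seen, averaged 160 ± 18.2 CPM in neonatal and 303 ± 28.5 CPM in adult LICs (SD, n = 3 each, log2 fold change -0.92 ± 0.27, SE, edgeR adjusted p = 0.233). It fell in the fit without neonatal replicate 4 (log2 fold change -0.83, edgeR adjusted p = 0.0487, range over 22 alternatives 0.000153 to 0.694). NK cell markers had 2 tested members, too few for a test (median 1.06), and the 13 mitochondrially encoded genes were absent from the file. The remaining lists not called were interferon response (median 0.07, camera adjusted p = 0.554), NF-kB and inflammatory (-0.09, 0.780), chemokines and receptors (-0.74, 0.110), heat shock (0.28, 0.655), unfolded protein response (-0.06, 0.718), p53 targets (-0.22, 0.636) and cholesterol synthesis (-0.06, 0.780). Ccl5, a chemokine gene, had 13 counts over the adult and 8 over the neonatal libraries. The camera direction was downward for interferon response and mitosis and upward for NF-kB against these medians, and B lymphoid genes had a mean of -0.89 with a downward camera direction.

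Ribosomal protein and oxidative phosphorylation genes depended on neonatal replicate 4. With all 6 libraries all 75 ribosomal protein genes had a positive log2 fold change (median 0.42, camera adjusted p = 0.655) and so did 40 of 44 oxidative phosphorylation genes (median 0.34, camera adjusted p = 0.636). On the voom values that camera tests, these medians were 0.08 and 0.01. Without that replicate the medians were -0.47 and -0.39, and both lists were lower in neonatal LICs (camera adjusted p = 1.47e-10 and 0.00471, adjusted p = 0.958 for each with an estimated correlation). Without neonatal replicate 7 or 8, both lists were instead called higher in neonatal LICs. Ribosomal protein genes share reads with many pseudogenes.

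**Figure D3:**
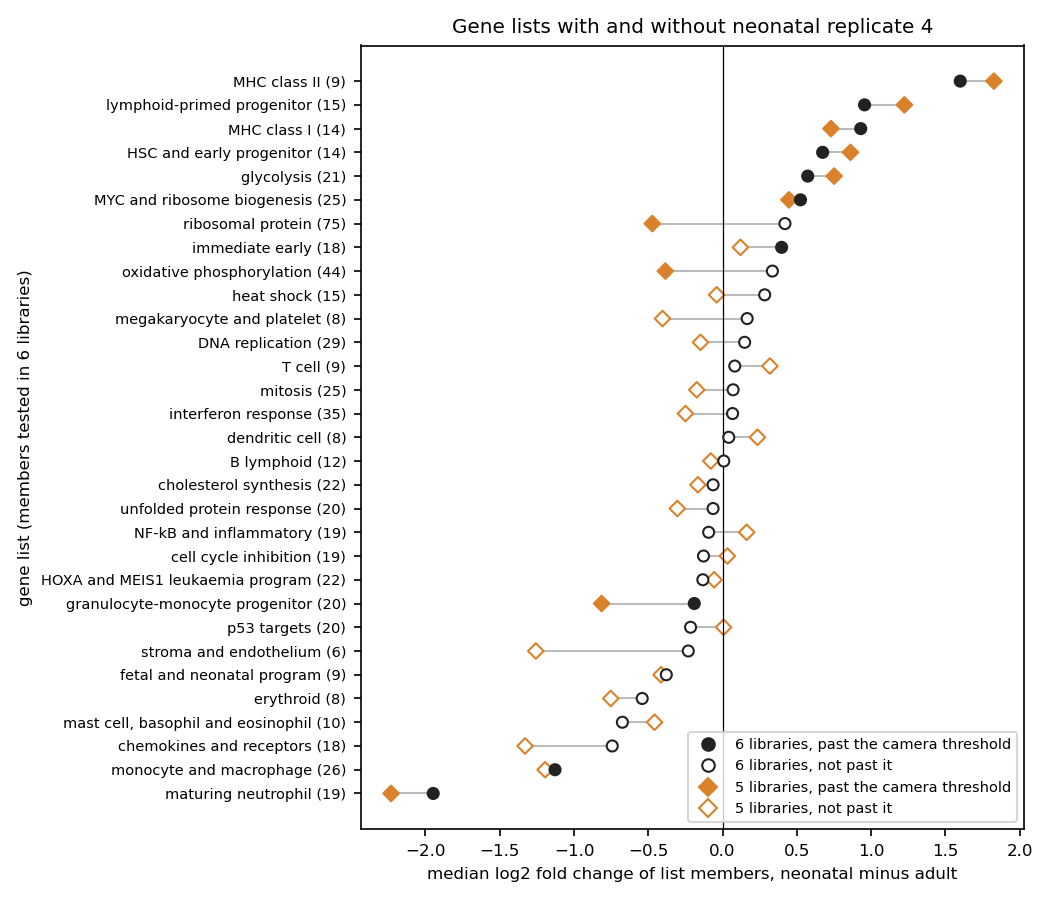
Median log2 fold change (neonatal minus adult) of the members of 31 gene lists, 1 line per list with the number of members tested in brackets. Circles stand for all 6 libraries and diamonds for the 5 libraries without neonatal replicate 4, filled where the list passed camera with its preset correlation. MHC class II (1.60 and 1.83) and maturing neutrophil (-1.95 and -2.23) lie at opposite ends in both, and ribosomal protein genes move from 0.42 to -0.47.

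Without neonatal replicate 4, 516 genes were higher in neonatal and 312 higher in adult LICs (edgeR's quasi-likelihood test, adjusted p under 0.05), 803 of them outside chromosomes X and Y, and all 7 genes called with 6 libraries were among them. The replicate left out did not bear out the rises: of 477 such genes with a mean of at least 5 CPM, it lay above all adult libraries for 121 (25.4%), against 35.2% of 8994 genes not called. Of 278 genes that fell, it lay below all adult libraries for 165 (59.4%), against 41.9% of those not called. Neonatal replicate 4 also differed from neonatal replicates 7 and 8 along exon length and GC content. This check therefore cannot tell a lack of replication from a bias of that library or of neonatal replicates 7 and 8. In this fit, chosen for naming after the low depth was seen, the genes with the largest rise that were also tested in all 6 libraries included Faah, which encodes an enzyme that degrades endocannabinoids, Susd5 and Slamf6, a lymphocyte receptor gene. Susd5 was at 46.3 and 106 CPM in neonatal replicates 7 and 8, at 0 to 0.863 CPM in adult LICs and at 0.897 CPM in neonatal replicate 4. Slamf6 was at 1.35 and 4.84 CPM in neonatal replicates 7 and 8, at 1.49 CPM in neonatal replicate 4 and at most 0.0446 CPM in adult LICs. The largest falls outside the sex chromosomes, after Cftr, included Ica1, Clec3a and Azgp1, with 0 counts in all 3 neonatal libraries and means of 9.35 ± 7.80, 4.32 ± 3.34 and 4.13 ± 3.86 CPM in adult LICs (SD, n = 3), at least 426-, 202- and 198-fold lower over the group. S100a8 also passed (log2 fold change -8.53, edgeR adjusted p = 0.0437, range over 22 alternatives 4.94e-10 to 0.405).

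DESeq2 on all 6 libraries called 785 genes, 297 of them shared with the 5-library calls, and limma with library quality weights called 1056. All 3 fits called 285 genes, 131 higher in neonatal and 154 higher in adult LICs. The 3 fits reuse the same libraries, and quality weights were added after the low depth of neonatal replicate 4 was seen. Their overlap is therefore not a replication. Among genes given above without a call on 6 libraries, Fcnb, H2-DMa, H2-Oa, H2-Q6, Psmb8, Dusp2 and Cd68 passed in 5 of 22 alternatives. Ngp, Camp, S100a9, Gata2, Cd300lf and Irf8 passed in 4 of 22, Cd34 in 3 of 21 and Prdm16 in 1 of 21. At an unadjusted p under 0.05, edgeR's quasi-likelihood test on 6 libraries had 1585 genes, 654 higher in neonatal and 931 higher in adult LICs.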

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

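Alternatives with quality weights, thinning, length and GC offsets, or neonatal replicate 4 left out together with another test were chosen after the data were seen. With 7 genes called by edgeR's quasi-likelihood test (2 higher in neonatal, 5 in adult LICs), DESeq2 called 785 (334 and 451), edgeR's likelihood ratio test 594 (225 and 369), limma with quality weights 1056 (537 and 519), DESeq2 without that replicate called 3448 (1800 higher in neonatal and 1648 in adult LICs), and edgeR with length and GC offsets 11 (6 higher in neonatal); the cause was not tested. With chromosomes X and Y left out before the fit, 0 genes passed (0 higher in neonatal, 0 in adult) of 12848, where 1527 had an unadjusted p under 0.05 in edgeR. Removing the sex-linked genes takes away 5 of the 7. The other 2, Cftr and Pi15, had the largest unadjusted p of the 7 (2.53e-05 and 2.56e-05, edgeR's quasi-likelihood test). Benjamini-Hochberg adjustment depends on the rank of each p, so their calls rested on the sex-linked genes ranked ahead of them. Pi15 was not called with RLE factors, upper quartile factors or library sizes without the top 50 genes, which left 1 gene higher in neonatal LICs in each. Cftr was not called with RLE factors, library size alone or library sizes without the top 50 genes. Scaling moved the median of all genes by at most 0.059. Leaving out each library in turn gave 1 to 828 genes, 0 to 516 higher in neonatal and 1 to 312 higher in adult LICs, with edgeR, the highest without neonatal replicate 4. The 0 higher in neonatal LICs occurred without adult replicate 1, 2 or 4, where 489, 538 and 608 had an unadjusted p under 0.05. All libraries thinned to the lowest depth gave 7 genes and 10 lists. Of 10 lists called by camera, 0 were called with an estimated correlation, 1 by fry (MHC class I) and 0 without neonatal replicate 4 with an estimated correlation, which takes the members' shared spread into account, and 7 to 11 when each library was left out. Log2 fold changes near 0 turned sign, none of them called: Hmga2 (0.48) was -0.19 in limma voom, -0.36 with quality weights and -0.30 in DESeq2 without neonatal replicate 4, and -0.31 to 0.89 with each library left out. Meis1 (0.14) was -0.39 to 0.53 and Csf1r (0.20) -0.40 to 0.62 with each library left out, and Csf1r was -0.011 with length and GC offsets. No called list turned, and lists not called, with voom medians near 0 in most, turned in median or in test direction in 74 values; for these and for Hmga2, Meis1 and Csf1r the cause was not tested. With library size alone these were B lymphoid -0.0047, ribosomal protein -0.030 and oxidative phosphorylation -0.065. With RLE factors this was cell cycle inhibition 0.016. Without a filter these were DNA replication 0.062, cell cycle inhibition 0.0053 and oxidative phosphorylation -0.0097. With at least 1 CPM in 3 libraries these were chemokines and receptors 0.47 and p53 targets 0.045. With quality weights these were HOXA and MEIS1 leukaemia program -0.14, DNA replication -0.050, cell cycle inhibition 0.032, p53 targets 0.031, ribosomal protein -0.31, oxidative phosphorylation -0.28 and cholesterol synthesis -0.13. With all libraries thinned these were erythroid 0.11, mast cell -0.36, mitosis 0.074, NF-kB and inflammatory -0.064, chemokines and receptors 0.73 and unfolded protein response 0.0053. With length and GC offsets these were B lymphoid -0.14, stroma and endothelium -0.13, mitosis 0.18, cell cycle inhibition 0.046, NF-kB and inflammatory 0.031, ribosomal protein -0.046 and oxidative phosphorylation 0.011. Without neonatal replicate 4 and with an estimated correlation these were B lymphoid -0.027, megakaryocyte and platelet -0.11, stroma and endothelium -0.26, HOXA and MEIS1 leukaemia program -0.083, DNA replication -0.085, cell cycle inhibition 0.14, heat shock 0.0056, p53 targets 0.038, ribosomal protein -0.45 and oxidative phosphorylation -0.39. With each library left out in turn the medians, with all libraries in brackets, were B lymphoid (0.01) -0.53 to 0.53, T cell (0.43) 0.11 to 0.80, erythroid (-0.54) -1.06 to 0.0099, megakaryocyte and platelet (0.55) -1.30 to 1.63. Further ranges were stroma and endothelium (0.036) -0.72 to 0.74, HOXA and MEIS1 leukaemia program (-0.20) -0.35 to 0.017, DNA replication (0.062) -0.15 to 0.28, mitosis (-0.047) -0.18 to 0.12. Further ranges were cell cycle inhibition (-0.0044) -0.22 to 0.14, NF-kB and inflammatory (0.034) -0.11 to 0.33, heat shock (0.073) 0.0056 to 0.29, unfolded protein response (-0.18) -0.29 to 0.025. Further ranges were p53 targets (-0.11) -0.36 to 0.038, ribosomal protein (0.082) -0.45 to 0.41, oxidative phosphorylation (0.0068) -0.39 to 0.30, cholesterol synthesis (-0.072) -0.17 to 0.13. Of the other values for genes, 1508 kept direction and side of the threshold, 240 came to pass and 32 ceased to pass; for lists these were 366, 7 and 45. No paired analysis was possible because the groups share 1 replicate number. Without TMM scaling, the floor of 3 counts for a gene with 0 counts in neonatal replicate 4 was 0.763 CPM.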

Other observations

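Genes of the fetal and HOXA programs showed values outside the named-gene rule, all chosen after their values were seen. Lin28a, an RNA-binding protein gene of embryonic and fetal cells, was at 18.76, 18.59 and 12.29 CPM in adult replicates 1, 2 and 4 and at 1.793, 4.758 and 10.99 CPM in neonatal replicates 4, 7 and 8 (log2 fold change -1.45, edgeR adjusted p = 0.415). Cdkn1c, an imprinted inhibitor of cell division, averaged 42.6 ± 19.2 CPM in adult and 12.9 ± 3.14 CPM in neonatal LICs (SD, n = 3 each, edgeR adjusted p = 0.195). The means of both were higher in adult LICs. Neither passed in edgeR's main test, and of 22 alternatives 0 called Lin28a and 4 called Cdkn1c (DESeq2 on 6 libraries at adjusted p = 0.0153, range 0.00863 to 0.472). Pbx3, which encodes a partner of HOX proteins, averaged 162 ± 129 CPM in neonatal and 26.6 ± 21.4 CPM in adult LICs (SD, n = 3 each, edgeR adjusted p = 0.248, called in 4 of 22 alternatives).

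Of the tests below, those of sex and of carried neutrophils were chosen after the data were seen, and the others were written down before their values were computed.

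The difference between the age groups was weighed against chance and sex. The 6 libraries can be split in 10 ways into 3 and 3. The share of splits with at least as many called genes therefore cannot go below 0.1. The real split gave 7 genes, the highest other 0, and 1 of 10 splits reached the real count. Only the real split sets the sexes apart, so the sex-linked genes could separate without overlap in no other split. With chromosomes X and Y left out before the fit, the real split also gave 0 genes. The count of 7 therefore does not weigh age against chance. In those other splits 82 to 1437 genes had an unadjusted p under 0.05 in edgeR, against 1585 in the real split. Of the 7 genes 2 lay outside chromosomes X and Y. Every adult library carried Y-linked RNA and every neonatal library Xist RNA, so a difference of an autosomal gene such as Flt3 could come from sex, from age or from the separate leukaemias, and these data cannot tell them apart.

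The small number of genes called with neonatal replicate 4 in the fit (7 against 828 without it) was not explained by its depth. Neonatal replicate 7 thinned to that depth left a median of 838 called genes over 20 draws (790 to 896), and correlated with neonatal replicate 8 at 0.942, 0.0771 above the 0.865 of neonatal replicate 4. The ratio of neonatal replicate 4 to neonatal replicates 7 and 8 followed exon length (Spearman rho = -0.378, against at most 0.341 in other libraries, a maximum that arises where neonatal replicate 4 is in the comparison) and GC content (rho = -0.407), which is consistent with RNA or library quality that acts by length or GC content, or with a true difference of that leukaemia. This ratio does not say whether neonatal replicate 4 or neonatal replicates 7 and 8 departed. Removing length and GC trends gave 11 genes, so these trends were not the whole cause. No biological explanation was tested.

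The lower maturing neutrophil genes in neonatal LICs were weighed against neutrophils carried in the adult sorts and against GC and length bias. A single foreign source keeps its genes in 1 ratio, and the log2 ratio of adult replicate 2 to adult replicate 4 had an SD of 1.19 over 18 members, from -0.08 for Cxcr2 to 3.87 for Mmp9. That SD met the bound of 1 set against carried cells, but the result was taken as unable to tell after the values were seen, because 10 of the 18 members stood in neonatal LICs at 0.25 or more of the adult level and LICs' own expression can widen the SD. With length and GC trends removed the list's median was -2.08 against -1.95 before, and so not within 0.5 of 0 as such a bias required. A bootstrap over the 19 members gave a 95% interval of -4.99 to -0.84, which passes the bound of -1. That interval treats the members as independent and leaves out the spread between libraries, so it does not by itself exclude such a bias. Granulocytic maturation within adult LICs therefore remains possible and not told apart from carried cells.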
